A study of Mus musculus with 20 samples.

How the data were processed

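Total RNA of mouse hypothalamus was depleted of ribosomal RNA and sequenced as 20 paired-end libraries, per the labels. Genotype, WT (C57BL/6J) or KO (deletion of both Magel2 and Ndn), and time, day (6 h after light on) or night (18 h), give 4 groups of 5 libraries: WT_day, WT_night, KO_day and KO_night. Genotype is given alike by title and genotype field in every library. Time was taken from the first letter of the title, and for KO_day 5, whose title has no such letter, from the time field. In 6 libraries (WT_night 1, KO_day 1, KO_day 2, KO_night 1, KO_night 2 and KO_night 3) the time field contradicts the title, and no library was moved because of its values. WT_day 5 carries a title number that is already taken and was given the number that is otherwise missing. Nothing in the labels says that the libraries come from separate animals, so each p measures the spread between these samples.

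The deposited values are raw counts per gene, which the authors made with HISAT2 alignment to mm10 and featureCounts, per the submitters' processing notes. No version, annotation release or strand setting is recorded. Of the 53801 genes in the tables, 53706 matched the GENCODE M21 annotation (GRCm38) by identifier, from which symbols, positions and gene lengths were taken, and 37304 had a count. The libraries are strand-specific per the labels, but the counts were checked and are not separated by strand. Of 420 protein-coding genes inside a gene of the same strand 99.8% had 0 counts, against 5.2% of 803 inside a gene of the opposite strand and 13.3% of 12001 that overlap no gene. In 510 pairs of genes on opposite strands the count of the outer gene was at least 0.9 of that of the inner gene in all but 1. Overlapping and antisense genes and near-identical copies are therefore reported as uncertain. These zeros and shared counts also point to reads counted over whole gene spans. Levels may thus include intronic reads, whose share was not measured.

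Library totals ran from 32066289 to 48697647 counts. Intervals on single values are exact (Clopper-Pearson) at 95%, and a count of 0 allows up to 3 counts of the total. Both cover counting error only, since the reads carry no molecular identifiers. Duplicated libraries were checked in the 40 pairs within groups by chi-square per degree of freedom over genes with at least 20 summed counts, which ran from 5.58 to 53.7, so no 2 libraries differ by counting error alone.

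Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr with a minimum count of 10, 22181 genes tested) in R 4.3.3, with 1 fit of 4 group means to all 20 libraries. Its contrasts were KO against WT averaged over both times, by day and at night, night against day in WT and in KO, and the interaction of genotype and time. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and "rose" and "fell" are used only of genes and lists that passed. Levels are CPM values from library totals scaled by TMM factors (0.945 to 1.08), and the common biological coefficient of variation was 0.0918. Where another scaling was run, the median log2 change of all genes stayed within 0.1 of 0.

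In addition, 37 gene lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the lists, and again with an estimated correlation. They cover the Prader-Willi region (PWS list, tested without Magel2 and Ndn), other imprinted genes, clock genes highest in the light phase, clock genes highest in the dark phase and other clock genes, activity-induced immediate early genes, feeding peptides and receptors, the oxytocin and vasopressin system, the reproduction and growth axis, suprachiasmatic nucleus markers, serotonin receptors and enzymes, secretory granule proteins, WASH, retromer and MAGEL2 ligase partners, p53 targets, heat and cold shock genes, glucocorticoid-induced genes, the unfolded protein response, cholesterol synthesis, interferon-stimulated genes, and mitochondrially encoded and ribosomal protein genes. The rest are markers of neurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelium, pericytes and smooth muscle, tanycytes and ependyma, choroid plexus, pituitary, meninges and fibroblasts, blood, thalamus, cortex and hippocampus, and striatum, and sex-linked genes. The lists, tests, named-gene rule and alternatives, except those named at the end as added, were fixed before the data were examined.

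Named genes are Magel2, Ndn, the tested PWS list members and, of the genes that passed with a mean CPM of at least 1 and a symbol that is not a clone name, those with the largest rises and falls (10 of each for the averaged effect and for night against day, 5 of each for the KO effect by day and at night), with up to 4 members of each list by p. Some genes that this rule names are not reported here. Genes named outside this rule were chosen after their values were seen, and these are Gm32061, Gm7394, Gm3198, Gm18908, 9330162G02Rik and the other clone-named calls on chromosome 7. The clock check is the mean log2 CPM (pseudocount 0.5 CPM) of 5 dark-phase genes minus that of 5 light-phase genes in each library. Per3, Mkrn3 and Snurf, which lie inside or overlap other genes, had 0 counts and were not tested.

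The tests were tested on simulated counts with 200 changed genes. In the averaged comparison over 22181 genes the edgeR test recovered 78% of changes of 1.25-fold, 92% of 1.5-fold and 100% of 2-fold, and in the night comparison 56%, 86% and 98%. In the interaction these shares were 22%, 66% and 90%. The spread was drawn for each gene on its own, without a structure shared by genes within a library. These shares therefore need not hold for the real libraries. A trend with gene length was also added to the simulated WT_night libraries. Of the night calls 99 of 267 were then of unchanged genes, and 20 of 189 after its removal.

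The alternatives chosen in advance were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile scaling, no filter on low counts, a mean CPM of at least 1, the replicate number as a block, time from the time field, only the 14 libraries whose time labels agree, only the 2 groups compared, genotype alone, fry and an estimated correlation for lists, and for gene tests leaving out each library in turn. Added after the data were seen were removal of each library's trend with gene length (lowess, span 0.3), the same without the library labelled WT_day 3, a fit without WT_night 1, 2 and 3, leaving out each library for the lists and for the comparison of both KO effects, the clock check with a midpoint per genotype, and levels of Ndn and Magel2 without the library labelled WT_day 3. Group labels were also redrawn in 100 splits per comparison. Single values and correlations used scipy 1.17.1 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6), with 100000 permutations where an exact test was not feasible, and figures used matplotlib 3.10.9. All tests are two-sided.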

Results

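The libraries measure RNA of the hypothalamus in mice that lack both Magel2 and Ndn (KO) and in C57BL/6J mice (WT). The deletion is a model of Prader-Willi syndrome, a disorder of feeding, growth, sleep and behaviour that follows the loss of paternally expressed genes. Each genotype has 5 libraries from the day, 6 h after light on, and 5 from the night, 18 h after it. Totals ran from 32066289 to 48697647 counts per library, and mitochondrial rRNA made up 15% to 22.6% of them. Changes are log2 values with their standard error, levels are TMM-scaled CPM with their SD (n = 5 per group unless stated), and adjusted p values of genes are those of edgeR.

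Ndn (ENSMUSG00000033585, chromosome 7, 62346569 to 62350262 in GRCm38), which encodes the MAGE-family protein necdin, stood at 282 ± 41.5 in WT_night and at 263 ± 11.5 in the 4 other WT_day libraries without the library labelled WT_day 3. Its level was 0.528 ± 0.209 in KO_day and 0.608 ± 0.267 in KO_night, with 9 to 39 counts per KO library, or 0.0908% to 0.371% of the mean of 9 WT libraries. Magel2 (ENSMUSG00000056972, chromosome 7, 62377010 to 62381640), which encodes a partner of ubiquitin ligases in endosomal protein sorting, stood at 18.2 ± 1.04 in WT_night and 16.4 ± 1.03 in these 4 WT_day libraries. It was at 0.0740 ± 0.0609 in KO_day and 0.0982 ± 0.0713 in KO_night, with 0 to 7 counts per KO library. In KO_night 5 Magel2 had 0 counts, where 3 counts would be 0.0911 CPM.

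The library labelled WT_day 3 goes against its label at both deleted genes. Its Ndn level was 31.0 (1480 counts), 11.3% of the mean of the 9 other WT libraries, 273 ± 31.8 (n = 9), and its Magel2 level was 2.16 (103 counts), 12.4% of theirs. The 95% interval on the library total was 28.9 to 32 CPM for Ndn and 1.73 to 2.57 CPM for Magel2. Its Ndn level was 30.6 times that of the highest KO library. With it the WT_day means were 217 ± 104 for Ndn and 13.6 ± 6.44 for Magel2. The library stays in its labelled group, so directions drawn from WT_day include it unless the text says otherwise. Gm32061, a lincRNA on the opposite strand that spans both genes (62337794 to 62423245), stood at 295 ± 31.9 in the 9 other WT libraries and 1.23 ± 0.330 in KO. Its level exceeded the sum of Ndn and Magel2 by 0.738% to 2.56% in these WT libraries, so its own RNA is uncertain.

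**Figure D1:**
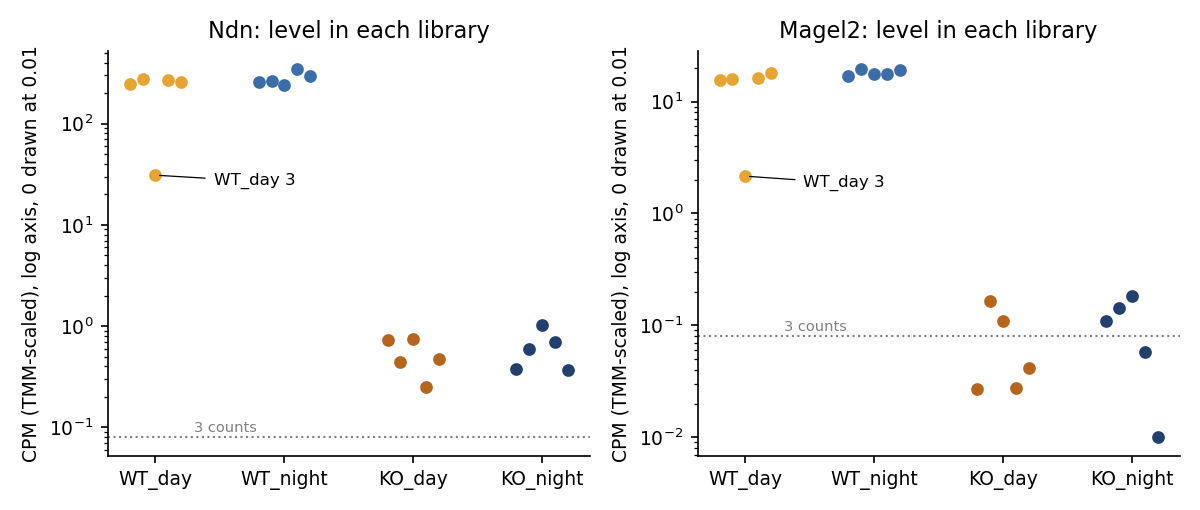
Ndn and Magel2 in each of the 20 libraries (TMM-scaled CPM, log axis), by group. The library labelled WT_day 3 lies at 31.0 for Ndn and 2.16 for Magel2, between the other WT libraries and the KO libraries.

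Which genes does the double deletion change at either time? Oxt, the gene of oxytocin (chromosome 2, 130576173 to 130577054), rose by 0.48 ± 0.0691 (1.4-fold, adjusted p = 8.3e-04) in KO averaged over both times, from 218 ± 34.3 by day and 176 ± 19.3 at night in WT to 252 ± 26 and 297 ± 35.0 in KO. Its neighbour Avp, the gene of vasopressin, rose by 0.33 ± 0.0747 (1.26-fold, adjusted p = 0.032), and Otp, a transcription factor of the neurons that make these peptides, rose by 0.26 ± 0.0602 (adjusted p = 0.036). Of the 8 genes of the oxytocin and vasopressin list 3 rose, none fell and 5 did not pass, 3 also when adjusted over the list alone, and the list rose in camera (adjusted p = 0.0125, and 0.512 with an estimated correlation). The library labelled WT_day 3 had the highest Oxt level of the WT libraries, 271, and without it the Oxt change was 0.53 (adjusted p = 4.86e-05). Avp did not pass with only the libraries whose time labels agree (adjusted p = 0.182), with genotype alone (0.0688) or without WT_night 1, 2 and 3 (0.316).

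**Figure D2:**
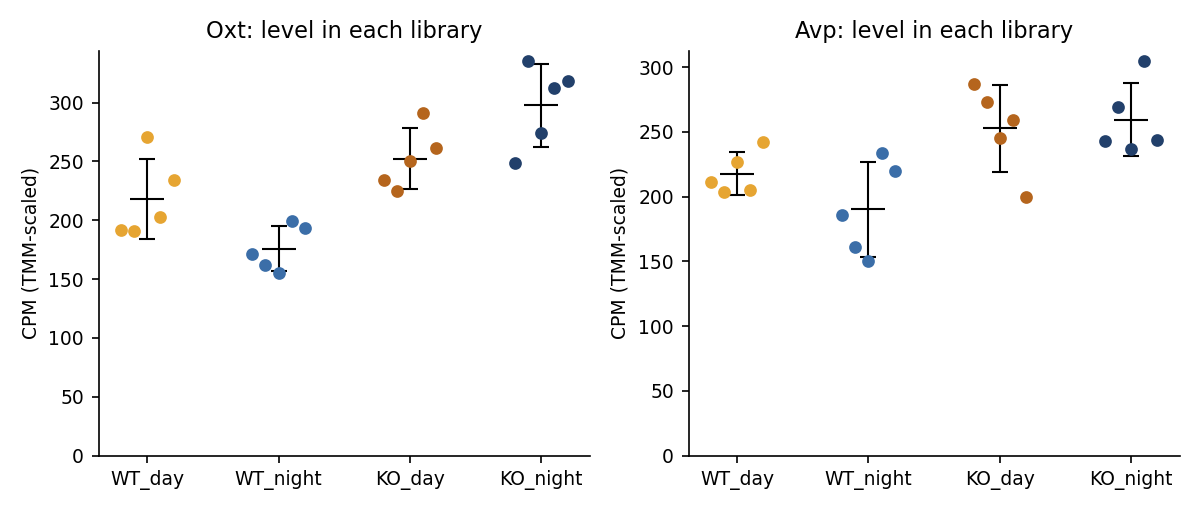
Oxt and Avp in each of the 20 libraries (TMM-scaled CPM), with the mean and SD of each group. At night the 5 KO libraries lie at 249 to 335 for Oxt and the 5 WT libraries at 155 to 199.

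In the imprinted region of Prader-Willi syndrome the genes beside the deletion moved in both directions. Snrpn, a splicing factor of the same imprinted domain, rose by 0.40 ± 0.088 (1.32-fold, adjusted p = 0.0293), while Ube3a, the ubiquitin ligase of Angelman syndrome, fell by 0.23 ± 0.0405 (1.17-fold, adjusted p = 0.0081) and the GABA receptor gene Gabrg3 fell by 0.38 ± 0.074 (1.30-fold, adjusted p = 0.0186). Of the 16 tested genes of the PWS list 1 rose, 4 fell (with Ndn at -8.77 ± 0.351 and Magel2 at -7.44 ± 0.382) and 11 did not pass. Adjusted over the list alone 2 rose and 7 fell, and camera gave an adjusted p of 0.0982. Among the 11 are Peg12 at 0.60 (adjusted p = 0.135), Snhg14 at -0.20 (0.092), Atp10a at -0.19 (0.0765), Oca2 at -0.13, Gabra5 at -0.06, Nipa1 at -0.05, Nipa2 at -0.04, Tubgcp5 at -0.04, Cyfip1 at 0.05 and Herc2 at 0.01. Within 5 Mb before Ndn 12 of 36 tested genes passed (33.3%; 4 rose and 8 fell), against 0 of 37 within 5 Mb after Magel2 and 30 of 1590 (1.89%) in the rest of chromosome 7 (Fisher's exact p = 1.33e-11 for the stretch before Ndn against the rest). On other chromosomes 246 of 20483 genes passed (1.2%).

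Several of these 12 calls are uncertain, because their reads are shared with another gene. 9330162G02Rik (log2 change -0.49, adjusted p = 1.695e-05) overlaps Ube3a on the opposite strand, Gm44562 (-0.53) lies inside Ube3a on the opposite strand, and Gm18908 (0.75, adjusted p = 0.00111) lies inside Snrpn on the opposite strand. The count of Ube3a (mean 643 CPM) may in turn hold reads of 9330162G02Rik (mean 177 CPM), so the size of its own fall is uncertain too. The pseudogenes Gm7394 (-6.83) and Gm3198 (0.85) went opposite ways, from 1.76 to 0.0105 CPM and from 1.80 to 3.38 CPM, while their sum was 3.56 ± 0.745 in 9 WT and 3.39 ± 0.543 in 10 KO libraries (exact permutation p = 0.625). Each of these genes counts as a call of its own among the 12 and in the Fisher test, so that p is uncertain too. Gm44742 fell by 0.79, Gm44643 by 0.76 and Gm44644 by 0.22, and Gm9801 rose by 0.32. Snurf lies inside Snrpn on the same strand and had 0 counts. Whether its reads were dropped or counted at Snrpn is not known, so the level of Snrpn is uncertain too. Ube3a and Gabrg3 passed in each fit without 1 library, but neither passed without WT_night 1, 2 and 3 (adjusted p = 0.104 and 0.242) or with only the libraries whose time labels agree (0.108 and 0.164). With the trend with gene length removed the change of Gabrg3 was -0.23, and it still passed.

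**Figure D3:**
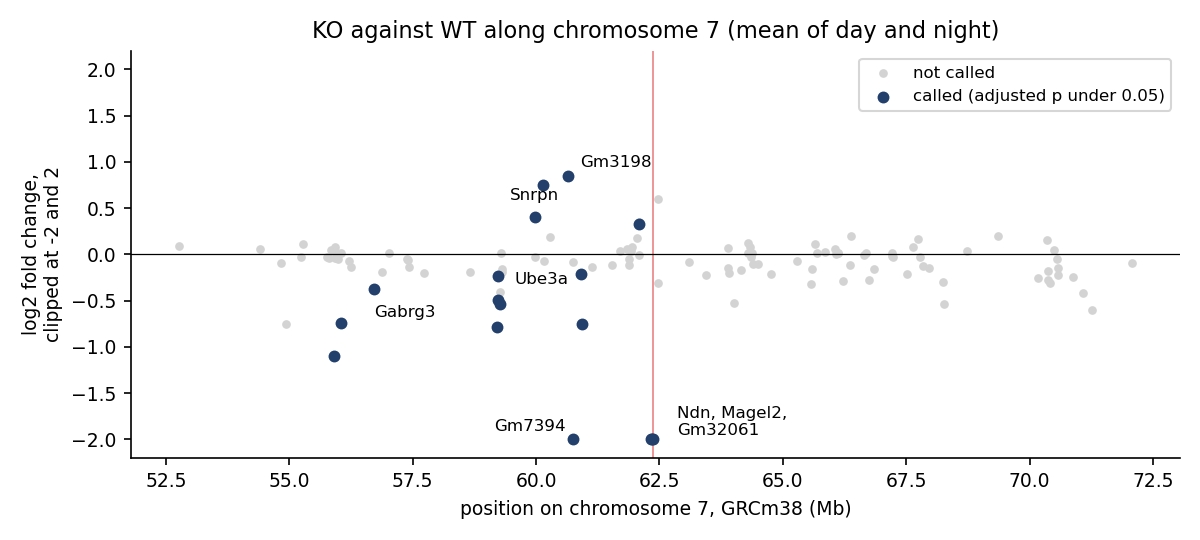
Log2 change of KO against WT, averaged over both times, for tested genes on chromosome 7 within 10 Mb of the deleted genes, by position (GRCm38, Mb), with values clipped at -2 and 2 and the deleted genes marked by a line. Within 5 Mb 12 of 36 genes before Ndn passed and 0 of 37 after Magel2.

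Beyond this region and Oxt, the largest rises in KO that are reported here, averaged over both times, were those of Ush1c, a scaffold protein of hair cells and photoreceptors, by 0.73 ± 0.175 (1.66-fold, adjusted p = 0.0383), Srp54b by 0.63 ± 0.149 (1.55-fold), Cox6a2, a muscle-type subunit of cytochrome oxidase, by 0.51 ± 0.109 (1.42-fold), and Hes5, a Notch target, by 0.39 ± 0.0791 (1.31-fold). Neurl2, Phf13 and Wif1 rose by 0.36, 0.34 and 0.33. Gxylt1, a glycosyltransferase, fell by 1.85 ± 0.458 (3.6-fold, adjusted p = 0.0463, and 0.0752 without the library labelled WT_day 3), but WT held 5 libraries at 13.6 to 17.2 CPM and 5 at 88.2 to 219, the library labelled WT_day 3 among the latter at 121, and all KO libraries lay at 14.1 to 32.6. Sult2b1 fell by 0.48 ± 0.11, Pzp by 0.45 ± 0.0999, and Tfcp2l1, Fam71d and Stab2 by 0.40 each, and Zfp951 fell by 0.38. In total 175 genes rose and 116 fell, 291 of 22181, and 194 passed without the library labelled WT_day 3 (178 of them among the 291). Without the library labelled WT_day 3 Ush1c (adjusted p = 0.053), Pzp (0.0514) and Tfcp2l1 (0.0561) did not pass, and with the trend with gene length removed Tfcp2l1 (0.0583) and Stab2 (0.0684) did not. Of the 22 calls named by size or from the PWS list 18 did not pass without WT_night 1, 2 and 3, 17 with only the libraries whose time labels agree and 17 with the time field. Counts were 19 without WT_night 1, 2 and 3, 58 with only the libraries whose time labels agree, 30 with the time field, 47 without KO_night 3 and 1265 without WT_night 4.

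Among the lists, cholesterol synthesis rose in KO averaged over both times (camera adjusted p = 2.7e-04, and 0.512 with an estimated correlation). Of its 17 genes 15 were higher and 1 rose, or 4 when adjusted over the list alone, and Srebf2, a regulator of the pathway, at 0.13 (adjusted p = 0.0505) did not pass. Markers of glia moved with it. Oligodendrocyte markers rose (camera 0.00229, 0.512 estimated; 8 of 8 higher, 1 rose, 3 over the list alone), with Mag, a myelin glycoprotein, at 0.26 ± 0.0568 (adjusted p = 0.03) and Cnp at 0.15 (0.0773). Astrocyte markers rose (0.0174, 0.512 estimated; 8 of 8 higher, none passed alone, 1 over the list alone), with Sox9 at 0.24 (0.0846). Of the other imprinted genes 2 of 34 rose, the calcitonin receptor gene Calcr by 0.28 ± 0.0539 (adjusted p = 0.0194) and Dlk1 by 0.19 (0.0417), and 4 rose and 1 fell over the list alone (camera 0.115). Single members passed in the dark-phase clock list (Npas2 fell by 0.28, camera 0.198), other clock genes (Bhlhe41 rose by 0.15, camera 0.0999), the reproduction and growth axis (the prolactin receptor gene Prlr fell by 0.24, camera 0.973), neuron markers (Gad1 rose by 0.14, camera 0.0582) and blood markers (Alas2 fell by 0.30, camera 0.436).

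In the remaining lists no member passed averaged over both times, though light-phase clock genes were higher in 5 of 5 (camera 0.0598), oligodendrocyte precursor markers in 6 of 6 (0.0614), and meningeal and fibroblast markers lower in 7 of 7 (0.0999). Adjusted over the list alone 2 light-phase clock genes and 2 p53 targets rose and 3 immediate early genes fell, and no other of these lists had more than 1 gene in either direction. Camera gave 0.607 for the 21 feeding peptides and receptors, 0.436 for immediate early genes, 0.306 for glucocorticoid-induced genes, 0.535 for the unfolded protein response, 0.198 for secretory granule proteins and 0.306 for WASH, retromer and MAGEL2 ligase partners. It gave 0.52 for suprachiasmatic nucleus markers, 0.394 for serotonin receptors and enzymes, 0.436 for p53 targets, 0.973 for heat and cold shock genes, 0.535 for interferon-stimulated genes, 0.436 for mitochondrially encoded genes and 0.518 for the 74 ribosomal protein genes. For tissue markers it gave 0.965 (microglia), 0.832 (endothelium), 0.52 (pericytes and smooth muscle), 0.684 (tanycytes and ependyma), 0.436 (choroid plexus), 0.52 (pituitary, where Prl was at -1.94 and Gh at -0.98), 0.436 (thalamus), 0.894 (cortex and hippocampus), 0.946 (striatum) and 0.198 (sex-linked genes). The test and the median differed in sign for heat and cold shock genes, endothelium, tanycytes, cortex and hippocampus, and striatum.

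By day, which genes does the deletion change while the animals rest? Srp54b, a signal recognition particle gene, rose by 1.24 ± 0.213 (2.36-fold, adjusted p = 0.0112), from 4.06 to 6.21 CPM in WT_day to 9.29 to 17.5 in KO_day. At night it was at 8.41 ± 3.39 in WT and 8.58 ± 1.55 in KO, so its averaged rise comes from the day. Celsr2, a planar polarity cadherin, rose by 0.39 ± 0.0631 (adjusted p = 0.0059), with Map1a at 0.42 ± 0.0764 (0.0175), Mtss1l at 0.38 ± 0.0675 (0.014) and Prr12 at 0.41 (0.0488). The activity-induced gene Fosb fell by 0.99 ± 0.195 (adjusted p = 0.0395), the endothelial gene Stab2 by 0.75 ± 0.132 (0.014), Apold1 by 0.64 ± 0.127 (0.0395) and the glucocorticoid target Tsc22d3 by 0.58 ± 0.11 (0.031). Of the 4 groups WT_day was the lowest for Srp54b, Celsr2, Map1a, Mtss1l and Prr12 and the highest for Fosb, Stab2, Apold1 and Tsc22d3. Celsr2 was at 62.7 CPM in WT_day, 80.7 in WT_night, 82.2 in KO_day and 88.9 in KO_night. Without the library labelled WT_day 3 Apold1, Prr12 and Tsc22d3 did not pass (adjusted p = 0.0805 for each). Ndn fell by 8.68 and Magel2 fell by 7.44. Oxt at 0.21 ± 0.0975 (0.496), Avp at 0.21 (0.53), Otp at 0.38 (0.0641), Ube3a at -0.11 (0.553), Gabrg3 at -0.17 (0.665) and Snrpn at 0.54 (0.0788) did not pass. Snrpn passed, however, without the library labelled WT_day 3 (0.64, adjusted p = 0.0423) and with the trend with gene length removed (0.52, 0.019). In total 14 genes rose and 11 fell, 27 passed without the library labelled WT_day 3 (20 of them among the 25), and counts without 1 library ran from 15 (KO_day 3 or KO_day 4 left out) to 73 (KO_day 2).

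By day 8 of 37 lists were called, 3 of them also with the time field. Glucocorticoid-induced genes fell (camera adjusted p = 8.42e-08, 0.288 with an estimated correlation; 12 of 12 lower, 1 fell, 8 over the list alone), and the unfolded protein response fell (2.42e-07, 0.412 estimated; 14 of 14 lower, none passed, 4 over the list alone). Immediate early genes fell (4.24e-06, 0.184 estimated; 19 of 20 lower, 1 fell, 4 over the list alone), as did ribosomal protein genes (2.74e-12, 0.742 estimated; 72 of 74 lower, none passed). Cholesterol synthesis rose (1.19e-06, 0.327 estimated; 17 of 17 higher, 1 rose), as did other imprinted genes (0.0023, 0.198 estimated; 25 of 34 higher, 4 over the list alone), other clock genes (0.0023, 0.0788 estimated; 3 over the list alone) and the oxytocin and vasopressin list (0.0409, 0.45 estimated; 1 over the list alone). The oxytocin and vasopressin list did not pass without WT_day 2, WT_day 4, KO_day 1 or KO_day 4 (camera adjusted p up to 0.117). Pituitary markers varied between these libraries, with Prl at -4.32, Gh at -3.21 and Fshb at -2.70 passing over the list alone, and Gh at 656 CPM in WT_day 1.

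At night, when mice are active, Oxt rose by 0.76 ± 0.0981 in KO (1.69-fold, adjusted p = 2.34e-04), and Avp rose by 0.45 ± 0.106 (0.0182). The stress and feeding peptides Crh and Npy rose by 0.52 ± 0.152 (0.0323) and 0.42 ± 0.137 (0.0472), and the leptin receptor gene Lepr fell by 0.39 ± 0.0926 (0.0185), so that 2 of 21 feeding genes rose and 1 fell (camera 0.339). Ube3a fell by 0.35 ± 0.0573 (0.00495) and Gabrg3 by 0.59 ± 0.105 (0.00659). Snhg14 fell by 0.37, Ndn fell by 8.85 ± 0.495 and Magel2 fell by 7.44 ± 0.526. In total 6 of 16 PWS genes fell (7 over the list alone, camera 0.0801) and 10 did not pass, Snrpn among these at 0.27 (0.152, but 0.42 and 0.0232 with the trend with gene length removed). Lpl, lipoprotein lipase, rose by 0.87 ± 0.201 (1.83-fold), Ush1c by 0.93 ± 0.255 (1.90-fold), and Cyp26b1, which breaks down retinoic acid, fell by 0.89 ± 0.254 (1.85-fold). Prlr fell by 0.45 ± 0.082 (0.0084). The clock genes Arntl and Npas2 fell by 0.28 ± 0.0623 and 0.43 ± 0.0977, and Nr1d1 rose by 0.16 (0.0335). The time labels of KO_night 1, 2 and 3 conflict, and these libraries were lower (Arntl 25.9 to 29.0 CPM, Npas2 13.9 to 17.1) than KO_night 4 and 5 (Arntl 31.1 and 30.2, Npas2 21.7 and 19.8). Oxt did not pass without WT_night 1, 2 and 3 (0.60, adjusted p = 0.152, with 2 WT_night libraries left) or with the time field (0.62, 0.245). Ube3a and Gabrg3 passed in neither of these nor with only the libraries whose time labels agree (0.196 and 0.294). With the trend with gene length removed Gabrg3, a long gene, was at -0.29 and still passed. For Avp, Crh, Npy, Lepr, Prlr, Arntl and Npas2 that fit is not reported here. Among genes that passed at night short ones mostly rose and long ones mostly fell. The changes of these 7 genes are therefore not shown to stand apart from that trend. Of the 14 calls at night named by size or from the PWS list 10 did not pass and 1 reversed without WT_night 1, 2 and 3, 11 did not pass with only the libraries whose time labels agree, and 12 did not with the time field. All 4 genes that passed with the time field fell, so none of the rises at night, those of Avp, Crh and Npy included, passed there. With only the libraries whose time labels agree 2 genes rose, Oxt among them.

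Other large changes at night rest on few libraries. The mitochondrial tRNA gene mt-Tc rose by 4.96 ± 1.6 (31.2-fold, adjusted p = 0.0451, and 0.0653 with the trend with gene length removed), with 119 CPM in KO_night 5, 2.88 in WT_night 3 and no more than 0.364 in the other night libraries, and without KO_night 5 its change was -2.82. Pole2 rose by 3.86 ± 1.3 (14.5-fold, adjusted p = 0.046, 0.054 without the library labelled WT_day 3 and 0.0639 with the trend with gene length removed) with 38.2 CPM in KO_night 1 and 22.3 in KO_night 4, mt-Ty fell by 3.43 ± 0.753 (10.8-fold) with 341 CPM in WT_night 5, and Slc17a7, a marker of cortex and hippocampus, rose by 2.07 ± 0.604 (0.0319) with 7.12 CPM in KO_night 1 and 3.55 in KO_night 2. Gxylt1 fell by 2.35 ± 0.659 (5.10-fold), and without WT_night 1, 2 and 3 its change was 0.18.

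Oligodendrocyte markers rose at night (camera adjusted p = 0.00474, 0.647 with an estimated correlation; 8 of 8 higher, 2 rose, 5 over the list alone), with Mag at 0.32 (0.0204) and Cnp at 0.25 (0.0205). Meningeal and fibroblast markers fell (0.0198, 0.647 estimated; 7 of 7 lower, 5 over the list alone), the unfolded protein response rose (0.0359, 0.73 estimated; 14 of 14 higher, with Hyou1 at 0.19) and ribosomal protein genes rose (0.00359, 0.799 estimated; 73 of 74 higher, none passed). Of neuron markers 3 of 9 rose (Gad1 by 0.21, Slc32a1 by 0.27, Eno2 by 0.19), and of astrocyte markers 2 of 8 (Aldh1l1 by 0.22, Aldoc by 0.24). The unfolded protein response did not pass without WT_night 1, 2 or 3 or KO_night 1, 2 or 5 (adjusted p up to 0.196), ribosomal protein genes without WT_night 3 or KO_night 2 (up to 0.32), and meningeal markers without WT_night 4 or KO_night 4 (up to 0.0628). With the trend with gene length removed ribosomal protein genes were lower (0.842) and the unfolded protein response did not pass (0.205). With only the libraries whose time labels agree 2 of the 4 lists kept their call, and 2 with the time field.

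Gene length tracked the changes at night. In the shortest quintile of protein-coding genes (297 to 10149 bp, 2322 genes with mean CPM of at least 5) the median change in KO was 0.131, and 422 rose and 5 fell. In the longest quintile (93203 bp and longer, 2322 genes) it was -0.151, and 14 rose and 759 fell. Over 11607 such genes the first component held 31.7% of the variance between libraries and had an absolute r of 0.671 with log2 length, across genes, which are not independent replicates. In total 1148 genes rose and 1501 fell at night (43.3% up). With only the 2 night groups fitted 111 rose and 446 fell (19.9% up), and with upper-quartile scaling 906 and 1680 (35% up). Calls numbered 2314 without the library labelled WT_day 3, 6 with only the libraries whose time labels agree, 4 with the time field, 11 without WT_night 1, 2 and 3, 122 without WT_night 3 and 4355 without WT_night 4. With the trend with length removed 682 rose and 497 fell (57.8% up), 918 of them among the 2649, and Snhg14 at -0.07 (adjusted p = 0.251) no longer passed.

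**Figure D4:**
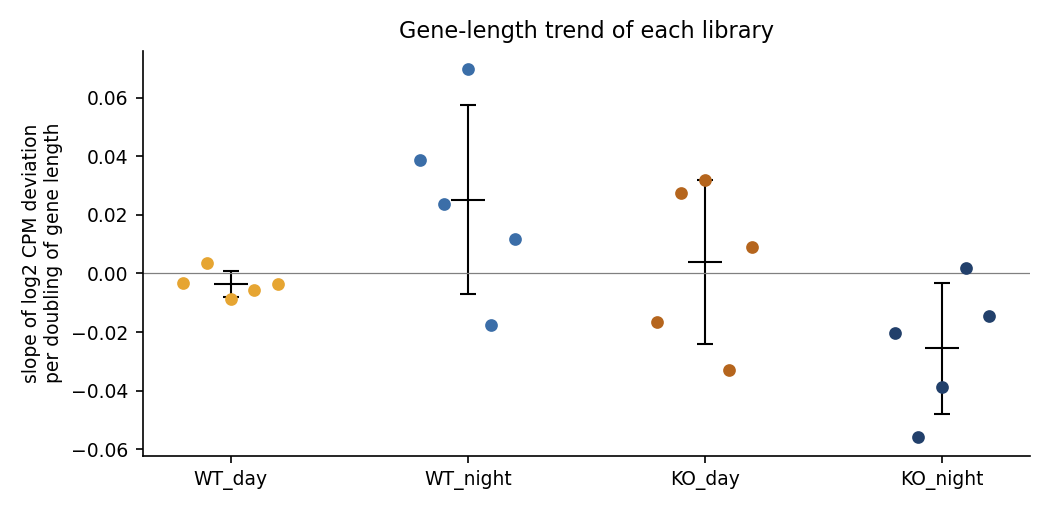
Slope of each library's log2 CPM deviation per doubling of gene length, by group, with the mean and SD of each group. The mean slope is 0.0252 in WT_night and -0.0255 in KO_night.

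In WT, which genes differ between night and day? The activity-induced gene Fosb fell at night by 1.78 ± 0.216 (adjusted p = 2.31e-04), from 1.61 to 0.468 CPM. Mt2, a metallothionein, fell by 0.91 ± 0.123 (1.88-fold, 9.67e-04), from 37.7 ± 8.24 to 20.1 ± 1.03. The glucocorticoid targets Zbtb16, Tsc22d3 and Mt1 fell by 0.96 ± 0.172 (0.0206), 0.57 ± 0.11 (0.0262) and 0.50 ± 0.0911 (0.0207). Of the clock genes Arntl rose by 0.32 ± 0.0622 (0.0262) and Dbp fell by 0.46 ± 0.101 (0.0498), and Vipr2, the receptor through which suprachiasmatic neurons stay in step, rose by 0.62 ± 0.137 (0.0498). Cyp26b1 rose by 1.56 ± 0.266 (2.96-fold), Gkn3 by 1.29 and Anpep by 0.81, with Mmp14, Plekho2, Frem2, Pla2g4a and Prr12 at 0.40 to 0.50. Fabp7 fell by 0.72, Txnip by 0.70, Apold1 by 0.68 and Icosl, Bc1, Nostrin and Smim3 by 0.57 to 0.62. In total 29 genes rose and 32 fell, but 12 passed without the library labelled WT_day 3, all 12 among the 61, and 16 of the 20 genes named by size did not pass. The count was 0 with the time field (edgeR, 2266 at an unadjusted p under 0.05), 9 without WT_day 5 and 9 without WT_night 1, 2 and 3.

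Clock genes highest in the light phase fell at night in WT (camera adjusted p = 1.18e-05, 0.00546 with an estimated correlation; 5 of 5 lower, 1 fell, 4 over the list alone), and immediate early genes fell (6.13e-09, 0.038 estimated; 17 of 20 lower, 1 fell, 10 over the list alone). Dark-phase clock genes rose (0.028, 0.327 estimated; 1 of 5, 2 over the list alone), and glucocorticoid-induced genes fell (3.1e-08, 0.327 estimated; 11 of 12 lower, 4 fell, 8 over the list alone). Ribosomal protein genes fell (2.4e-23, 0.612 estimated; 73 of 74 lower, none passed, 32 over the list alone), the unfolded protein response fell (0.0392, 0.85 estimated), cholesterol synthesis rose (0.028, 0.85 estimated) and meningeal markers rose (0.00133, 0.612 estimated; 7 of 7 higher, 2 over the list alone). Dark-phase clock genes did not pass without WT_night 4 or WT_night 5 (up to 0.0799), the unfolded protein response without WT_day 1, 2 or 3 or WT_night 1, 2 or 3 (up to 0.607), and cholesterol synthesis without WT_day 2, WT_night 1 or WT_night 4 (up to 0.109). With the trend with gene length removed dark-phase clock genes (0.166) and the unfolded protein response (0.267) did not pass. With the time field 6 of the 8 lists kept their call, and 6 with only the libraries whose time labels agree. Short genes were lower at night in WT (median -0.0848 in the shortest quintile of protein-coding genes).

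Clock genes also gave a check of the conflicting time labels. The difference between 5 dark-phase and 5 light-phase genes was -1.11 ± 0.099 in the 8 day libraries and -0.70 ± 0.082 in the 6 night libraries whose labels agree, and all 14 lay on their own side of the midpoint, -0.90. Of the 6 libraries with conflicting labels, WT_night 1 (-0.81), KO_day 1 (-1.08) and KO_day 2 (-1.10) lay on the side of the title, and KO_night 1 (-0.97), KO_night 2 (-1.01) and KO_night 3 (-1.16) on the day side, which is that of the time field. Title and time field are the same in the 14 libraries that set the midpoint. Only the 6 others can tell them apart, and 3 lie on the side of each. The midpoint of the agreeing KO libraries alone was -0.998. It has KO_night 1 on the night side and KO_night 2 close to it. Dbp was lower in KO_night 1 and 2 (26.1 and 26.7 CPM) than in any KO_day library (36.1 to 44.1), but not in KO_night 3 (36.5). Ciart was lower in KO_night 1, 2 and 3 (4.68, 5.37 and 4.44, against 5.87 to 6.99 in KO_day). The check was not run with the trend with gene length removed, so the share of that trend is unknown. The slope on gene length was -0.0202, -0.0559 and -0.0386 in KO_night 1, 2 and 3, and 0.0019 and -0.0146 in KO_night 4 and 5. The time of KO_night 1, 2 and 3 therefore stays open. By group the difference was -1.05 ± 0.048 in WT_day, -0.69 ± 0.086 in WT_night, -1.17 ± 0.079 in KO_day and -0.94 ± 0.162 in KO_night.

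**Figure D5:**
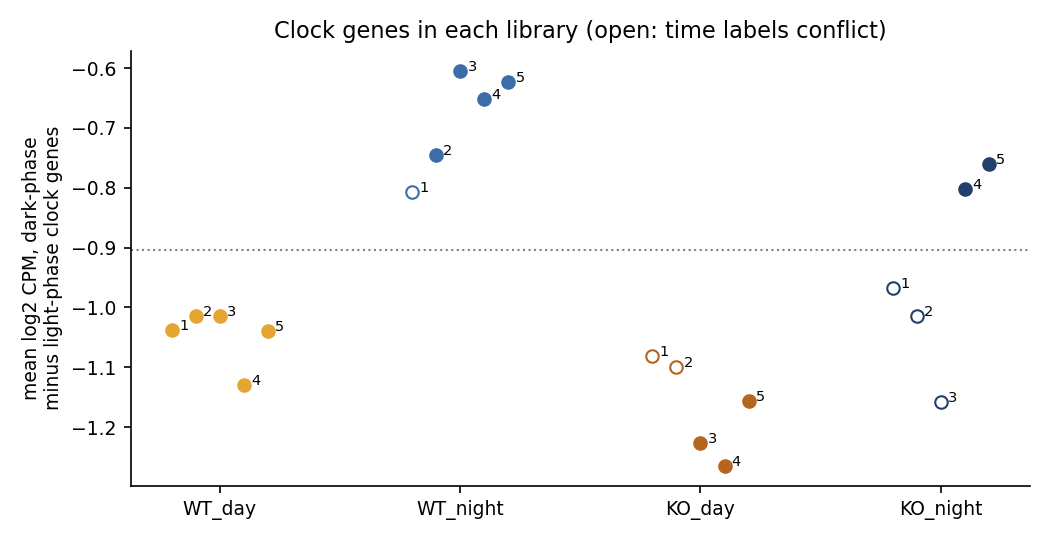
Clock-gene difference (mean log2 CPM of 5 dark-phase genes minus 5 light-phase genes) in each library, by group, with the midpoint of -0.90 and the libraries whose 2 time labels conflict marked. KO_night 1, 2 and 3 lie on the day side of it.

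In KO the same comparison addresses the day and night difference without the deleted genes. Htr1a, a serotonin receptor gene, rose at night by 0.35 ± 0.057 (1.28-fold, adjusted p = 0.022), the adenosine receptor gene Adora1 rose by 0.30 ± 0.0526 (1.23-fold, 0.0326), and Acot11 rose by 0.29. Ogfod2, Nsmf, Abhd8, Tyro3 and Klc2 rose by 0.22 to 0.34. The clock output gene Dbp fell by 0.51 ± 0.0997 (1.43-fold, 0.0489), from 39.3 ± 3.09 to 27.5 ± 5.48, the cilium gene Spag16 by 0.52 ± 0.0934 (0.0328) and Npsr1, the neuropeptide S receptor gene, by 0.44 ± 0.087 (0.0489). The time field moves KO_night 1, 2 and 3 to the day, but also KO_day 1 and 2 to the night, against the clock check. With it 0 genes passed (edgeR, 1516 at an unadjusted p under 0.05) and Htr1a (-0.0115), Ogfod2 (-0.0493), Nsmf (-0.0126) and Npsr1 (0.0825) turned sign. In total 12 genes rose and 4 fell, and 8 passed without the library labelled WT_day 3 (7 of them among the 16). In that fit 7 of the 12 genes named by size did not pass. The edgeR count was 0 without KO_day 2, KO_day 3, KO_day 5 or KO_night 2 (2568, 2862, 3300 and 2941 genes at an unadjusted p under 0.05) and 328 without KO_day 1. With only the 2 KO groups fitted it was 0 as well (3199 at an unadjusted p under 0.05), so none of the 12 named genes passed there.

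The unfolded protein response rose at night in KO (camera adjusted p = 7.51e-07, 0.446 with an estimated correlation; 14 of 14 higher, none passed, 8 over the list alone), and heat and cold shock genes rose (0.0247, 0.446 estimated; 6 of 11 over the list alone). Light-phase clock genes fell (0.0293, 0.202 estimated; 1 of 5, 3 over the list alone), as did other clock genes (0.0151, 0.115 estimated; 8 of 9 lower), the PWS list (0.0293, 0.446 estimated; 11 of 16 lower) and mitochondrially encoded genes (0.0408, 0.624 estimated; 3 of 13 over the list alone). Striatum markers rose (0.0293, 0.446 estimated, 3 of 7 over the list alone, with Adora2a at 0.92 ± 0.241). Of cortex and hippocampus markers 4 of 6 passed over the list alone, with Slc17a7 at 2.95 (0.0513). Slc17a7 was at 7.12 CPM in KO_night 1 and 3.55 in KO_night 2, but at 0.274 to 0.598 in the other KO_night libraries. None of the 7 lists called in KO was called with the time field, and 5 were with only the libraries whose time labels agree. With the trend with gene length removed the PWS list did not pass (0.32). Its count of 11 of 16 lower includes Magel2 and Ndn, which its test leaves out. The PWS list did not pass without KO_night 1 or KO_night 4 and light-phase clock genes without KO_day 4, KO_night 4 or KO_night 5 (each up to 0.0732), heat and cold shock genes without KO_night 1 (0.0779), striatum markers without KO_night 5 (0.127), and mitochondrially encoded genes without WT_night 4, KO_day 1, 4 or 5 or KO_night 1 or 4 (up to 0.27).

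Does the deletion change the difference between night and day? Oxt had an interaction of 0.55 ± 0.138 (adjusted p = 0.0598) and Crh of 0.99 ± 0.212 (0.0576). Tsc22d3 was at 0.88 ± 0.156 (0.0543) and Mt2 at 0.69 (0.0591), and none of these passed. They are not shown to stand apart from other genes, since 4910 genes had an unadjusted p under 0.05. Ube3a at -0.23 (0.108), Gabrg3 at -0.43 (0.109), Arntl at -0.34 (0.0641), Htr1a at 0.31 (0.0639) and Dbp at -0.05 (0.852) did not pass either, so their effects are not shown to differ between day and night or between genotypes. With edgeR 0 genes passed, with 4910 at an unadjusted p under 0.05, while DESeq2 called 1223 and limma-voom 2469. Glucocorticoid-induced genes rose in the interaction (camera adjusted p = 5.58e-06, 0.651 with an estimated correlation; 12 of 12 higher, 7 over the list alone), as did the unfolded protein response (1.45e-06, 0.651 estimated; 14 of 14, 10 over the list alone), immediate early genes (1.08e-04, 0.651 estimated; 19 of 20, 2 over the list alone) and ribosomal protein genes (1.88e-11, 0.651 estimated; 74 of 74). Meningeal and fibroblast markers fell (0.0187, 0.651 estimated; 7 of 7 lower, 3 over the list alone), but not without WT_day 4, WT_night 4 or 5, KO_day 1 or 4 or KO_night 4 (up to 0.103). Of these 5 lists 2 kept their call with the time field and 3 with only the libraries whose time labels agree. The WT_day libraries enter the KO effect by day, night against day in WT and the interaction alike. Calls of glucocorticoid-induced genes, immediate early genes, the unfolded protein response and ribosomal protein genes in these comparisons are therefore not separate evidence.

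Across the 22181 tested genes, which are not independent replicates, the KO effect by day and that at night had a Pearson r of 0.152 and a Spearman rho of -0.0347, and 47.4% of genes had the same sign. Without Magel2 and Ndn r was 0.0578. That value still includes Gm32061 (-7.63 by day and -7.89 at night) and Gm7394 (-6.53 and -7.13). How far the effects agree beyond these genes was therefore not measured. The sign of rho is not settled, as it ran from -0.158 without KO_day 4 (42.2% of the same sign) to 0.0966 without KO_day 2 (53.4%) and was 0.0149 with the trend with gene length removed. Of the 25 genes called by day 8 were also called at night, Magel2 and Ndn among them, all in the same direction, against 1.47 if the calls were independent. Without Magel2 and Ndn 6 of 23 were shared, and Gm32061 and Gm7394 were not left out of this count. Without 1 library the shared calls ran from 4 (WT_night 3 left out) to 21 (KO_day 2), and not all went the same way without WT_night 4 (15 of 16), KO_day 1 (7 of 8) or KO_night 4 (11 of 13).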

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

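The tests of the library labelled WT_day 3, of the pseudogene pair, of antisense counting and of a strain variant, and the removal of the trend with gene length, were chosen only after the result was seen. The splits of the samples were planned.

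Single libraries lay far from the others of their group in 14 of 96 groups (24 measures). Chance gives about 1 in 20 groups, but 7 of the 14 are of Gxylt1, Pole2, mt-Tc and mt-Ty, which are named for large changes that few libraries make, so the number is not compared with chance. The library labelled WT_day 3 stood apart for Ndn (31.0 CPM, others 248 to 274), Magel2 (2.16, others 15.6 to 17.9) and Ube3a (600, others 680 to 700). Mitochondrial rRNA was 15% in KO_night 4 (others 20.3% to 22%), and the clock-gene difference was -1.13 in WT_day 4 (others -1.04 to -1.01). Gxylt1 was at 29.1 CPM in KO_night 3 (others 14.1 to 15). Pole2 was at 7.46 in WT_day 4 (others up to 1.49) and 36.3 in KO_day 4 (others up to 1.29). The mitochondrial tRNA gene mt-Tc was at 18.2 in WT_day 1, 2.88 in WT_night 3 and 119 in KO_night 5 (others of their groups up to 0.844), and mt-Ty at 341 in WT_night 5 (others 6.55 to 44.3). The growth hormone gene Gh was at 656 in WT_day 1 (others 17 to 84.8) and 121 in WT_night 4 (others 2.12 to 24.1).

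The library labelled WT_day 3 has low Ndn and Magel2. A KO library under a wrong label is argued against by its Ndn level, 30.6 times that of the highest KO library. A loss of RNA of these 2 genes alone is argued against by the other genes called before Ndn. On a scale from KO (0) to WT (1) the library lies at 0.0625, the other WT libraries at 0.578 to 1.21 and the KO libraries at -0.142 to 0.33. Of 10 such genes 9 are within the KO range, and 7 are outside the WT range on the KO side. Some of the 10 share reads, so they are not 10 separate observations. RNA of a KO sample mixed with a smaller part of WT RNA cannot be told apart from WT RNA on the genes called off chromosome 7, because its position of 0.653 lies where the other WT (0.27 to 1.13) and the KO libraries (-0.388 to 0.806) overlap. The position before Ndn, 0.0625, would also go with such a mixture. Gxylt1, at 121 CPM against up to 32.6 in KO, goes against it, but is 1 gene that varies widely in WT. Such a mixture therefore stays open. An animal that carries the deletion on 1 allele, with partial expression of the other, stays open as untested.

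The KO effect called 2649 genes at night and 25 by day, and long genes fell while short genes rose. With the trend removed the real groups gave 1179 calls and 2 of 100 splits, the real one included, gave as many. That argues against the part of the trend that was removed as the whole cause. Length bias left after removal cannot be excluded, because the trend differs between the genotypes at night and would favour the real split. In simulated counts 20 of 189 calls were of unchanged genes after the removal. The highest other split gave 2132 calls, more than the real groups, and the reason was not tested. The mean slope on length was 0.0252 ± 0.0324 in WT_night and -0.0255 ± 0.0223 in KO_night, with the strongest correlations across genes in WT_night 3 (0.67) and KO_night 2 (-0.572). An effect of the deletion at night stays open, and so does a difference in RNA or handling of WT_night 1, 2 and 3, without which 11 genes passed with 2 WT_night libraries left, and wrong time labels, since 6 genes passed with only the libraries whose time labels agree and 4 with the time field.

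Calls beside the deleted genes lie on 1 side of them. Reads of Gm7394 counted at its near copy Gm3198 may explain the opposite changes of both, since the log2 ratio of their summed CPM was -0.071. Antisense reads counted without strand may explain the fall of Gm32061, of which at most 2.56% lies beyond Ndn and Magel2 in WT. A strain variant in the flank of the deletion cannot be told apart from an effect of the deletion on nearby genes, because 12 of 36 genes before Ndn but 0 of 37 after Magel2 passed, and a segment of another strain can end at the deletion. The effect of the deletion on Snrpn, Ube3a and Gabrg3 in the same domain stays open as untested.

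In 5 lists the KO effect at night differed from that by day by the interaction in camera: adjusted p was 1.08e-04 for immediate early genes, 5.58e-06 for glucocorticoid-induced genes, 1.45e-06 for the unfolded protein response, 1.88e-11 for ribosomal protein genes and 0.0187 for meningeal and fibroblast markers. None of the 5 held with an estimated correlation (adjusted p = 0.651 for each). The interaction uses the same WT_day libraries as the KO effect by day and as night against day in WT.

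Group labels were redrawn in 100 splits per comparison, with the real groups counted among them. At most 4 of 100 splits gave as many genes called as the real groups averaged over both times (real 291, highest other 1079, 2 splits with as many), by day (25, highest other 5, 1 split), at night (2649, highest other 2178, 1 split), in WT between night and day (61, highest other 1, 1 split) and in KO (16, highest other 1544, 4 splits). That argues against chance for these numbers but does not exclude it, since there was no adjustment over the comparisons. It is weakest in KO, where the count was also 0 without KO_day 2, KO_day 3, KO_day 5 or KO_night 2. For KO against WT the calls include the deleted genes, which set the real groups apart by design. The splits were not run without the deleted genes and those beside them. By day, where 25 genes passed, the splits therefore do not tell whether the other calls are beyond chance. For the interaction the splits decide nothing, since the real count is 0 and so all 100 splits give as many (highest other 306). Splits with 1079, 1544 and 306 calls exceed the real counts, and the reason was not tested. For the number of called lists chance cannot be excluded in any comparison: averaged 4 (highest other 14, 84 splits with as many), by day 8 (14, 29 splits), at night 4 (15, 78 splits), in WT 8 (12, 26 splits), in KO 7 (12, 50 splits) and in the interaction 5 (12, 74 splits).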

How the results depend on the processing

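Removal of the trend with gene length, alone or without the library labelled WT_day 3, the fit without WT_night 1, 2 and 3, leaving out each library for lists and for the r of both KO effects, clock midpoints per genotype, and target levels without the library labelled WT_day 3 were chosen after seeing the data. Counts of genes called were 291 (averaged), 25 (day), 2649 (night), 61 (night against day in WT), 16 (in KO) and 0 (interaction, 4910 at an unadjusted p under 0.05). In the same order they were 1052, 187, 3514, 387, 581 and 1223 with DESeq2 and 1324, 298, 3749, 859, 219 and 2469 with limma-voom. Without a filter day gave 60, WT 108, KO 70 and the interaction 105, and with a mean CPM of at least 1 WT gave 98, KO 26 and the interaction 63. The replicate numbers do not pair the samples: 7 of 30 same-number pairs had r over 0.1 (median -0.0124) and 4 of 20 libraries correlated best with their own number. With the replicate block counts were 215, 48, 1689, 43, 11 and 0 (edgeR, 4543 unadjusted). Time from the time field gave 30, 149, 4, 0 (2266 unadjusted), 0 (1516) and 0 (989), and only libraries whose time labels agree, with fewer libraries, gave 58, 89, 6, 104, 11 and 0 (2138). The 2 groups compared alone gave 127 by day, 557 at night, 383 in WT and 0 in KO (3199 unadjusted), and genotype alone gave 37 averaged. The length trend removed gave 59 by day, 1179 at night, 98 in KO and 8 in the interaction, and without the library labelled WT_day 3 as well 914 at night, 9 in WT and 32 in KO. Without WT_night 1, 2 and 3 counts were 19 averaged, 11 at night, 9 in WT, 138 in KO and 1 in the interaction. RLE and upper-quartile scaling kept every count within 1.5 times. Apart from fewer libraries or another set of genes tested, the cause was not tested. Sex as a covariate was not run, because Xist was near 0 and Y-linked genes were expressed in each group.

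Without 1 library the averaged count ran from 47 to 1265: 127 without WT_day 1, 58 without WT_day 2, 133 without WT_day 5, 61 without WT_night 1, 88 without WT_night 3, 1265 without WT_night 4, 120 without KO_day 1, 988 without KO_day 2, 86 without KO_day 4, 106 without KO_day 5, 47 without KO_night 3 and 612 without KO_night 4. By day it ran from 15 to 73 (WT_day 5 16, WT_night 4 61, KO_day 1 53, KO_day 2 73, KO_day 3 15, KO_day 4 15, KO_night 2 66, KO_night 4 72, KO_night 5 50). At night it ran from 122 to 4355 (WT_night 1 286, WT_night 3 122, WT_night 4 4355, KO_night 2 295, KO_night 3 513, KO_night 4 4253). In WT it ran from 9 to 179 (WT_day 1 18, WT_day 2 27, WT_day 3 12, WT_day 4 27, WT_day 5 9, WT_night 1 37, WT_night 2 17, WT_night 3 15, WT_night 5 35, KO_night 2 123, KO_night 4 179). In KO it ran from 0 to 328 and moved with every library: without WT_day 1 to 5 it was 7, 6, 8, 10 and 4, without WT_night 1 to 5 8, 6, 86, 127 and 9, without KO_day 1 to 5 328, 0, 0, 41 and 0, and without KO_night 1 to 5 2, 0, 52, 4 and 10. The interaction ran from 0 to 1555 (WT_day 2 8, WT_night 2 1, WT_night 4 1555, KO_day 1 474, KO_day 3 3, KO_day 4 717, KO_night 3 6, KO_night 4 1512).

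Called lists numbered 4, 8, 4, 8, 7 and 5, with an estimated correlation 0, 0, 0, 2, 0 and 0, and with fry 1, 1, 1, 4, 2 and 0. With only libraries whose time labels agree 9 lists were called averaged and 7 at night, with the length trend removed 9 averaged, and with the time field 3 in KO, none of them among the 7. Without 1 library the averaged number ran from 4 to 9 (9 without WT_night 3 or KO_day 4), day from 7 to 10, night from 2 to 6 (2 without WT_night 3 or KO_night 2), WT from 6 to 9, KO from 6 to 11 (11 without KO_day 3) and the interaction from 4 to 7, and called lists kept their direction in 20 of 20 such fits. The r of the KO effects by day and at night, 0.152, was 0.211 with a mean CPM of at least 1 and 0.0578 without Magel2 and Ndn, and without 1 library ran from 0.0653 to 0.213. Gm32061 and Gm7394 were kept in each of these values.

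Levels of Ndn and Magel2 moved by less than 1 SD on library totals, while without the library labelled WT_day 3 the WT_day means went from 217 to 263 for Ndn and from 13.6 to 16.4 for Magel2, and RLE scaling left every library on its side of the clock midpoint. With a midpoint per genotype only KO_night 1 changed sides. Of 22 named calls averaged over times Oxt, Ndn, Magel2, Ube3a and Gabrg3 passed in all 20 fits without 1 library, of 10 by day Srp54b, Celsr2, Mtss1l, Ndn and Magel2, of 14 at night Oxt, Ndn, Magel2, mt-Ty, Ube3a and Gabrg3, of 20 in WT Mt2 and 1 other, and of 12 in KO none. Most were lost without KO_night 3 (16 averaged), KO_day 3 (4 by day), WT_night 1 (8 at night), WT_day 3 (16 in WT) and KO_day 2 (12 in KO). Signs reversed at night for mt-Tc without KO_night 5 (-2.82) and Gxylt1 without WT_night 1, 2 and 3 (0.18), and in KO with the time field for Htr1a (-0.0115), Ogfod2 (-0.0493), Nsmf (-0.0126) and Npsr1 (0.0825). The highest change of mt-Tc without 1 library was 6.97, of unchanged sign (without WT_night 3). Depth limits Magel2 and Ndn in KO, at 0 to 39 counts per library.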

Other observations

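The correlations below were chosen only after the result was seen. Oxt and Avp were compared with each other and with Otp and Sim1, transcription factors of the neurons that make both peptides, as deviations from the group means in all 20 libraries (5 relations, 100000 permutations, Benjamini-Hochberg adjusted). Oxt and Avp had a Pearson r of 0.459 (permutation p = 0.0438, adjusted 0.219) and a Spearman rho of 0.567 (permutation p = 0.0156, adjusted 0.078), and r was 0.493 over the 18 libraries left without the 2 farthest. Oxt and Otp had an r of 0.126 (permutation p = 0.634, adjusted 0.792) and a rho of 0.158 (0.536, adjusted 0.699), with r = 0.151 without the 2 farthest. For Oxt and Sim1 r was 0.0399 (0.874, adjusted 0.874) and rho 0.0842 (0.746, adjusted 0.746), with r = 0.362 without the 2 farthest. For Avp and Otp r was 0.248 (0.341, adjusted 0.597) and rho 0.155 (0.559, adjusted 0.699), with r = 0.236 without the 2 farthest. For Avp and Sim1 r was 0.251 (0.358, adjusted 0.597) and rho 0.232 (0.386, adjusted 0.699), with r = 0.262 without the 2 farthest. No relation passed after adjustment.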
